A study of Homo sapiens with 12 samples.

How the data were processed

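The deposited values were linear intensities from single-colour arrays, and per the labels each labelled cRNA was hybridised to its own slide. The software and steps that the authors used for image analysis, background and normalization are not given in the sources used here. That the deposited intensity of a probe had been scaled by the authors to the median of its array was inferred from the values, because the median intensity of every array lay close to 1 and some values lay at or below 0. The series description gives the culture and labelling: cells near confluence were kept 24 h without serum and treated for 48 h, RNA was cleaned on columns with DNase, and biotinylated cRNA was made from total RNA and stained with a single fluorescent dye. The code −9999 was read as missing; it stood in 0.716% of the values, and a further 1.10% lay at or below 0 and were also set to missing before the log2 step. The files carry no detection calls and no marks for control spots, so no probe was removed on those grounds.

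Of 54359 probes, 53671 had a value on at least 2 arrays of every group and were tested, 48012 had a value on all 12 arrays, and 356 had no positive value. The gene table listed 23472 probes with 1 gene, 905 with several and 29982 with none. Symbols came from that table by Entrez identifier for 23434 probes. A gene was represented by its single-gene probe with the highest mean over the 12 arrays. IL1B, IL1RN and IL1R1 had no such probe. Array medians differed by at most 0.05 on the log2 scale, under the limit of 0.1 set for quantile normalization, so no further scaling was applied.

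Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with moderated two-sided tests, 8 residual degrees of freedom, and Benjamini-Hochberg adjustment over all probes tested. A probe or gene was called at an adjusted p under 0.05. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so single genes rest on the limma model. Each of 26 gene lists was tested against the other genes with limma camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated per list and the rotation test fry were alternatives. Fry tests a list against no change and not against the other genes, so its results answer a different question. Counts "adjusted over the list alone" used the members of 1 list as the family of tests. Errors of log2 changes are standard errors from limma, and those of group values are SDs.

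The tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. For each comparison with vehicle the rule took the 10 largest increases and 10 largest decreases among called genes whose groups did not overlap on any array, and 5 each way for the other comparisons. From each list it took up to 4 called members with the largest change or, where none was called, the member with the lowest p. TNF, IL1B, IL1RN, IL1R1, TNFRSF1A, TNFRSF1B, TERT, ACTB and GAPDH were always to be given where measured.

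The labels give replicates 1, 2 and 3 as the same passages in each group, so arrays with the same number share a passage. After removal of group means the 18 pairs of arrays with the same number had a mean residual correlation of 0.018 (−0.541 to 0.720), against 0.0046 for the 36 pairs with different numbers. That mean hides differences between comparisons. Same-number vehicle and TNFα arrays gave 0.618, 0.201 and 0.720, and same-number vehicle and IL1β arrays 0.210, −0.339 and −0.541. The protocols name no block. The main fit therefore had none, and a fit with the passage as a block was an alternative.

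The alternatives were quantile normalization, median centring, an offset of 0.104 before the log, removal of dim probes, probes with all 12 values, 1 probe per gene, a variance prior with trend and robust settings, array quality weights, the passage block, a fit of the compared groups alone, and leaving out each array or passage. Leaving out the 3 arrays that lay apart on the first principal component, and using its score as a covariate, were chosen after seeing the data.

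In a self-test with simulated groups of 3 arrays and 53671 probes, limma recovered 8% of 50 probes changed 2-fold, 38% of those changed 4-fold, 66% at 8-fold and 80% at 16-fold. It made 3 false calls there and 0 calls in an unchanged simulated comparison. In simulated genes drawn independently of each other, the 1 shifted list was called and 0 unshifted lists were. That simulation held no correlation between genes, so it could not show false list calls that such correlation gives.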

Results

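T-HESC is a line of human endometrial stromal cells immortalised with telomerase. Its cultures received vehicle, tumour necrosis factor alpha (TNFα) at 5 ng/ml, interleukin 1 beta (IL1β) at 1 ng/ml, or both cytokines at those doses, for 48 h after 24 h without serum. Total RNA from each culture was labelled and hybridised to its own single-colour CodeLink whole-genome array. There were 12 arrays in 4 groups of 3, and the replicates of a group were separate passages of the line: passage 13 (replicate 1), passage 28 (replicate 2) and passage 15 (replicate 3). The stated aim was to find genes whose expression differed with these cytokines, which are studied in connection with endometriosis. Values were log2 scaled intensities, and the number of arrays per group, 3, limited the precision of every comparison.

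The arrays measured 53671 probes well enough to test, 23194 of them listed with 1 gene, which covered 18106 genes. Between 52944 and 53507 probes per array had a positive signal. The first principal component took 47.9% of the variance and did not order the arrays by treatment. Vehicle replicate 3 (score 97.6), TNFα replicate 3 (61.3) and IL1β replicate 2 (48.3) lay at its high end, vehicle replicate 1 lay at −83.7, and the remaining 8 arrays lay between −21.5 and −8.75. The second component took 17.3% of the variance. On it the 3 vehicle arrays scored −53.7 to −32.9, the 6 single-cytokine arrays −2.66 to 11.4 and the 3 arrays with both cytokines 30.1 to 35.0. Vehicle replicate 3 had the lowest median Spearman correlation with the other arrays, 0.924, against 0.944 to 0.968 for the rest.

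**Figure D1:**
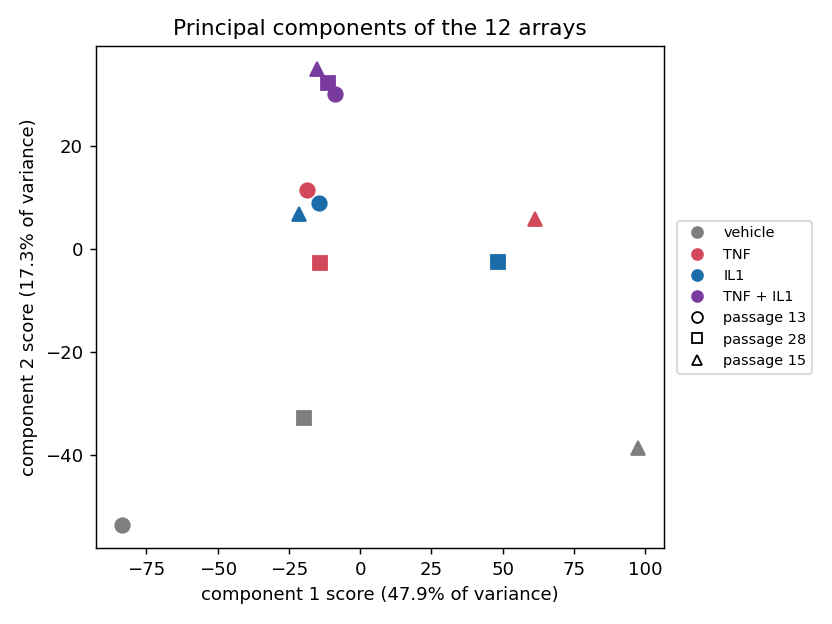
Scores of the 12 arrays on the first (x axis, 47.9% of variance) and second (y axis, 17.3% of variance) principal components, in score units, with colour for the treatment and marker shape for the passage. The arrays with both cytokines lie at 30.1 to 35.0 on the second component and the vehicle arrays at −53.7 to −32.9.

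TNFα was compared with vehicle first. It raised HSD11B1, the enzyme that regenerates cortisol from cortisone, by 5.73 ± 0.47 on the log2 scale (SE, n = 3 per group; adjusted p = 0.00319), and mitochondrial superoxide dismutase SOD2 by 3.96 ± 0.29 (adjusted p = 0.00319). The chemokine CCL5 rose by 6.18 ± 0.67 (adjusted p = 0.0255; vehicle n = 2) and the monocyte attractant CCL2 by 2.93 ± 0.38 (adjusted p = 0.0425). The cytokine IL32 (4.13 ± 0.33), the lipolysis inhibitor G0S2 (3.98 ± 0.48), the lysosomal protease CTSS (3.38 ± 0.30), the antiviral membrane protein BST2 (3.09 ± 0.39), the receptor tyrosine kinase ligand ALKAL2 (2.99 ± 0.26) and the interleukin subunit EBI3 (2.83 ± 0.31) rose as well. Their adjusted p ran from 0.00319 to 0.0353. The imprinted gene MEST fell by 2.91 (adjusted p = 0.0303) and CRABP2, which carries retinoic acid to its nuclear receptors, fell by 2.62 (adjusted p = 0.0147). In all, limma called 25 of 53671 probes, 22 higher and 3 lower. Among them were the representative probes of 14 genes, 12 higher and 2 lower, and other probes of IFI27 and of the glutamate receptor subunit GRIA3 (2.13 ± 0.28, adjusted p = 0.0432), both chosen after their values were seen. A second HSD11B1 probe rose by 5.40, while a second SOD2 probe, of lower signal, gave 0.16 and did not pass. With the passage as a block, 13 probes passed and CCL5 (adjusted p = 0.111), CCL2 (0.129) and EBI3 (0.0926) did not. Leaving out 1 array gave 22 probes (vehicle replicate 1), 23 (vehicle 2), 13 (vehicle 3), 10 (TNFα 1), 42 (TNFα 2) or 15 (TNFα 3). In that order it ended 4 of 12, 4 of 11, 5 of 11, 7 of 12, 0 of 12 and 7 of 12 named calls (adjusted p = 0.0525 to 0.137). The calls of HSD11B1, IL32, SOD2, CTSS and ALKAL2 held whichever 1 array was left out. In the main limma fit 3784 probes had an unadjusted p under 0.05, where chance gives 2684. A fit of the 6 arrays alone called 0 probes (2669 at unadjusted p under 0.05, no more than by chance). A fit without the 3 arrays that lay apart, an alternative chosen after seeing the data, also called 0 probes (5945).

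By gene list, camera with the preset correlation called 8 of 26 lists for TNFα, 7 higher and 1 lower. With an estimated correlation 0 passed, and with fry 4 did. Other splits of the same 6 arrays gave up to 7 lists at the preset correlation. Of 42 measured interferon-response genes 1 rose by its representative probe, BST2, and 14 rose when adjusted over the list alone, with none falling. IFI27, another member, was called on its second probe (3.36 ± 0.41, adjusted p = 0.0271) and not on its representative probe (3.30 ± 0.51, adjusted p = 0.0827). On every array, 18 were higher and 2 lower with TNFα than on any vehicle array, where chance gives 2.1 each way. The median change was 0.60 (limma camera, adjusted p = 3.5e-17; adjusted p = 0.116 with an estimated correlation). Of 27 NF-kB pathway and feedback genes 1 rose (SOD2), and 8 rose adjusted over the list alone, with a median of 0.74 (adjusted p = 6.05e-17; adjusted p = 0.113 with an estimated correlation). Chemokines had 2 of 21 members up, CCL5 and CCL2, and 6 adjusted over the list alone (median 0.64, adjusted p = 3.09e-07; adjusted p = 0.178 with an estimated correlation). Inflammatory cytokines had 2 of 25 up, IL32 and EBI3, and 9 adjusted over the list alone (median 0.30, adjusted p = 1.48e-08; adjusted p = 0.0632 with an estimated correlation). No member passed among 36 cytokine receptors and signalling genes, such as the receptor CD40 (1.88 ± 0.27, adjusted p = 0.0643), nor among 18 genes of MHC class I presentation, such as the immunoproteasome subunit PSMB10 (1.26 ± 0.30, adjusted p = 0.323). As lists both were higher (medians 0.44 and 0.55, adjusted p = 2.79e-06 and 8.03e-08; adjusted p = 0.279 and 0.0632 with an estimated correlation), with 4 and 5 members up adjusted over the list alone. Cholesterol and fatty acid synthesis (21 genes, 0 past, none adjusted over the list alone, median 0.33, adjusted p = 0.0123) passed as a list too. So did cell cycle (45 genes, 0 past, none adjusted over the list alone, median −0.39, adjusted p = 0.0158). They had adjusted p = 0.525 and 0.722 with an estimated correlation. The cholesterol call did not hold without passage 13 (adjusted p = 0.236) or passage 15 (0.123) or without the 3 arrays that lay apart (0.155), and without passage 28 the cell cycle list tested as higher (adjusted p = 0.272). The other 18 lists did not pass. Of these, structural extracellular matrix passed as lower without passage 15 (adjusted p = 0.00915) or the 3 arrays that lay apart (0.00114), epithelial markers as lower (0.0167) and angiogenesis as higher (0.0415) without passage 13, and decidualization as higher without passage 28 (0.0496). Without dim probes structural matrix passed as lower (0.0294) and angiogenesis (0.0433) and oxidative stress (0.0302) as higher.

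IL1β alone was compared with vehicle next. It raised HSD11B1 by 4.87 ± 0.47 (SE, n = 3 per group; adjusted p = 0.0227) and SOD2 by 3.49 ± 0.29 (adjusted p = 0.0123), and these 2 genes, with a second HSD11B1 probe at 4.51, made up all 3 probes called, none lower. CXCL8, the neutrophil attractant interleukin 8, stood at 9.10 ± 0.13 with IL1β (SD, n = 3) against 4.51 ± 0.36 with vehicle, a difference of 4.59 ± 0.57 that did not pass (adjusted p = 0.132), although with 1 probe per gene, and so fewer tests, it did (adjusted p = 0.0453). The alarmin IL33 (3.49 ± 0.59, adjusted p = 0.225) and CTSS (2.19 ± 0.30, adjusted p = 0.139) did not pass either. The median change of all probes was −0.13, against −0.05 with TNFα, and 5191 probes had an unadjusted p under 0.05, against 2684 by chance. With the passage as a block, SOD2 was not called (adjusted p = 0.0594) and both HSD11B1 probes were. Leaving out vehicle replicate 1, vehicle replicate 2 or IL1β replicate 2 gave 0 probes with limma (6599, 5375 and 4125 at unadjusted p under 0.05) and IL1β replicate 3 gave 1. HSD11B1 missed the threshold whichever 1 of the 6 arrays was left out (adjusted p = 0.0577 to 0.136) and SOD2 without vehicle 1, vehicle 2 or IL1β 2 (adjusted p = 0.0570 to 0.0667). limma called 0 probes in the 6 arrays alone (2937 at unadjusted p under 0.05) or without the 3 arrays that lay apart (7277).

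The IL1β list results were led by chemokines, with a median change of 1.36 over 21 genes. Of these 0 passed, 6 rose adjusted over the list alone, and 10 were higher on every IL1β array than on any vehicle array, where chance gives 1.05 (camera adjusted p = 5.75e-17; adjusted p = 0.0573 with an estimated correlation). NF-kB genes had 1 of 27 up, SOD2, and 6 adjusted over the list alone (median 0.74, adjusted p = 1.63e-15; adjusted p = 0.1402 with an estimated correlation). Inflammatory cytokines had 0 of 25 past and 4 up adjusted over the list alone (median 0.44, adjusted p = 7.6e-09; adjusted p = 0.0573 with an estimated correlation). Cytokine receptors (36 genes, 1 up adjusted over the list alone, median 0.07, adjusted p = 9.2e-05) and MHC class I presentation (18 genes, 0 adjusted over the list alone, median 0.13, adjusted p = 0.00237) passed with no member past. They had adjusted p = 0.273 and 0.205 with an estimated correlation. For the 42 interferon-response genes, 0 of which passed either way, the median was −0.01. Their mean was 0.12 and the test pointed up (adjusted p = 0.0171; adjusted p = 0.584 with an estimated correlation). Oxidative stress genes had SOD2 up of 26, also adjusted over the list alone, and a median of 0.12 (adjusted p = 0.0198; adjusted p = 0.155 with an estimated correlation). Matrix proteases and their inhibitors had 0 of 31 past, 1 up adjusted over the list alone and a median of 0.13 (adjusted p = 0.0218; adjusted p = 0.584 with an estimated correlation). Decidualization-associated genes had 0 of 34 past either way and a median of 0.16 (adjusted p = 0.0376; adjusted p = 0.273 with an estimated correlation). Epithelial markers were lower, with 0 of 12 past either way, a median of −0.59 and adjusted p = 0.0218 (adjusted p = 0.273 with an estimated correlation); keratin KRT18 stood at −0.88 ± 0.26 (adjusted p = 0.431). Of these calls, leaving out passage 13 ended oxidative stress (adjusted p = 0.134) and decidualization (0.341). Leaving out passage 28 ended interferon response (0.0921) and oxidative stress (0.210). Leaving out passage 15 ended receptors (0.265), MHC class I (0.265), decidualization (0.354), epithelial markers (0.736) and proteases, whose test then pointed down (0.779). Quantile normalization (0.132) and leaving out dim probes (0.0848) ended decidualization too. Without the 3 arrays that lay apart interferon response (0.0580), proteases (0.0643) and epithelial markers (0.349) did not pass. Cell cycle did not pass (median −0.29, adjusted p = 0.207) and tested as higher without passage 28 (adjusted p = 0.00443) and lower without passage 15 (adjusted p = 3.67e-06). Structural extracellular matrix did not pass (median −0.33, adjusted p = 0.364), and passed as lower without passage 15 (adjusted p = 5.13e-05) or the 3 arrays that lay apart (adjusted p = 0.000529). Adhesion molecules passed as higher without passage 28 (adjusted p = 0.0295). Without the 3 arrays that lay apart prostaglandin and leukocyte genes passed as higher and contractile genes as lower (adjusted p = 0.0389 for each), and cholesterol synthesis as lower (0.0148). Without dim probes prostaglandin (0.0291) and angiogenesis genes (0.0171) passed as higher, the latter also with the component 1 score as a covariate (0.0152).

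With both cytokines the response against vehicle was the widest of the 3. HSD11B1 rose by 7.12 ± 0.47 (SE, n = 3 per group; adjusted p = 0.000518) and SOD2 by 4.77 ± 0.29 (adjusted p = 0.000518). The neutrophil chemokines CXCL2 (6.52 ± 0.71, adjusted p = 0.00669) and CXCL8 (4.87 ± 0.57, adjusted p = 0.00944) rose. So did the mononuclear cell chemokines CCL5 (5.54 ± 0.67, adjusted p = 0.0164, vehicle n = 2) and CCL7 (4.66 ± 0.48, adjusted p = 0.00547). COXFA4L3, related to a subunit of mitochondrial cytochrome c oxidase, rose by 6.82 ± 0.70, the irritant-gated ion channel TRPA1 by 5.02 ± 0.69, the guanylate-binding protein pseudogene GBP1P1 by 4.64 ± 0.38 and G0S2 by 4.48 ± 0.48 (adjusted p = 0.00267 to 0.0206). MEST fell by 3.56 and CRABP2 by 3.13 (adjusted p = 0.00542 and 0.00337), and cardiac alpha actin ACTC1, integrin subunit ITGA4, the actin-capping protein CAPG and the serine protease CORIN fell by 2.84, 2.09, 1.76 and 1.70 (adjusted p = 0.00944 to 0.0483). ADAMTS18 (−3.18), TLE6 (−2.46), NCF4 (−2.45) and RTKN2 (−1.92) were also called lower, on dim probes that gave −1.05, −1.53, −1.33 and −1.42 after an offset was added before the log, where ADAMTS18 (both cytokines n = 2) no longer passed. limma called 133 probes, 101 higher and 32 lower. Among them were the representative probes of 63 genes, 52 higher and 11 lower, while 59 probes had no single gene and 52 lay below the median signal. Second probes of HSD11B1 (6.85), CTSS (4.34) and IFI27 (adjusted p = 0.00542) were called, while second probes, of lower signal, of KRT18 (−1.52, adjusted p = 0.0635), SOD2 (0.28), GBP1P1 (1.23), ITGA4 (−0.42), MAP3K8 (0.24) and TLE6 (−0.50) were not. The median change of all probes was −0.13.

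The same counts moved with the arrays used. With the passage as a block 87 probes passed, 73 of them among the 133, and 13 of the 38 genes named for this comparison did not pass. These were CCL5 (adjusted p = 0.0575), ADAMTS18 (0.0693), TLE6 (0.0812), NCF4 (0.0912), ITGA4 (0.111), CAPG (0.0526), ZC3H12A (0.0520), IFI44L (0.0513), IFI27 (0.0711), ICAM2 (0.0912), NINJ1 (0.0693), KYNU (0.107) and GCH1 (0.0564). Without vehicle replicate 1, 2 or 3 the count was 120, 114 or 137 and 11, 14 or 14 of the named calls ended. Without replicate 1, 2 or 3 of both cytokines it was 62, 27 or 47 and 18, 25 or 22 ended (adjusted p = 0.0503 to 0.186). HSD11B1, SOD2, COXFA4L3, CXCL2, CCL7, GBP1P1, G0S2, MEST, CRABP2, IL32, BST2 and CTSS passed whichever 1 array was left out. Without the 3 arrays that lay apart, 77 probes passed, 44 of them among the 133. In the 6 arrays alone 24 passed.

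**Figure D2:**
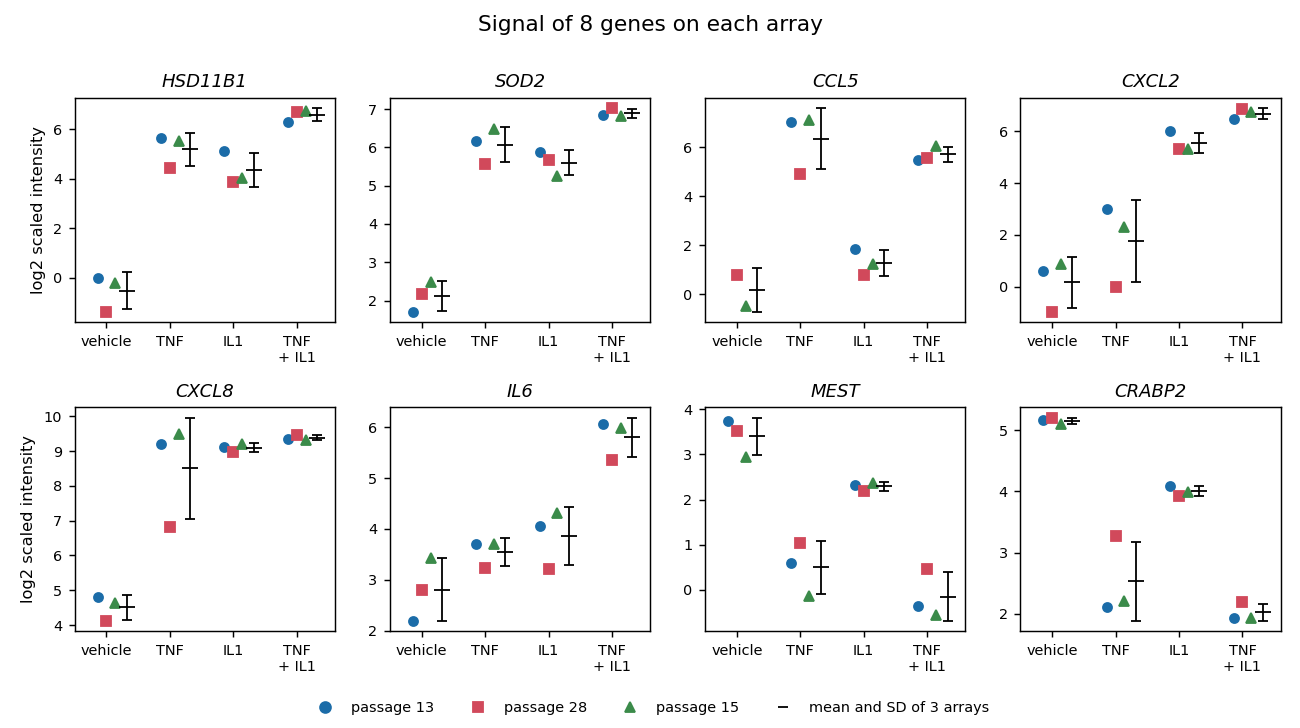
Log2 scaled intensity (y axis) of 8 genes on each array by treatment (x axis), with marker shape for the passage and black bars for the mean and SD of 3 arrays (2 for CCL5 with vehicle). HSD11B1 averages −0.53 with vehicle, 5.20 with TNFα, 4.34 with IL1β and 6.59 with both cytokines, and CRABP2 averages 5.15, 2.53, 4.01 and 2.02 in the same order.

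By gene list, the combination raised chemokines most. Of 21 genes 6 rose, 12 adjusted over the list alone, and 13 were higher on every array with both cytokines than on any vehicle array, where chance gives 1.05 (median 2.51, camera adjusted p = 2.4e-14; adjusted p = 0.0491 with an estimated correlation). Of 27 NF-kB genes 4 rose and 18 rose adjusted over the list alone (median 1.14, adjusted p = 1.06e-20; adjusted p = 0.0491 with an estimated correlation). Beside SOD2 these were the feedback inhibitor TNFAIP3 (3.16 ± 0.46), the kinase MAP3K8 (2.60 ± 0.37) and the ribonuclease ZC3H12A (1.98 ± 0.26), with adjusted p from 0.0177 to 0.0274. Of 25 inflammatory cytokines 4 rose and 10 rose adjusted over the list alone (median 0.72, adjusted p = 4.15e-11; adjusted p = 0.0491 with an estimated correlation). These were IL33 (4.36 ± 0.59), IL32 (3.39 ± 0.33), IL6 (3.00 ± 0.38) and EBI3 (2.57 ± 0.31), with adjusted p from 0.00472 to 0.0192. Of 42 interferon-response genes 5 rose and 18 rose adjusted over the list alone (median 0.64, adjusted p = 2.71e-20; adjusted p = 0.0648 with an estimated correlation). Among them were BST2 (4.10 ± 0.39), IFI44L (3.78 ± 0.61), IFI27 (3.61 ± 0.51) and EPSTI1 (2.53 ± 0.30), with adjusted p from 0.00470 to 0.0447. MHC class I presentation had 0 of 18 past and 2 up adjusted over the list alone (median 0.67, adjusted p = 2.57e-07; adjusted p = 0.0491 with an estimated correlation), HLA-G standing at 0.63 ± 0.16 (adjusted p = 0.169). Cytokine receptors had 0 of 36 past and 6 up adjusted over the list alone (median 0.57, adjusted p = 1.42e-08; adjusted p = 0.111 with an estimated correlation).

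Cell cycle was the list that moved down with both cytokines. None of its 45 genes passed, in either adjustment. However, 17 were lower on every array with both cytokines than on any vehicle array and 1 was higher, where chance gives 2.25 each way (median −1.01, adjusted p = 7.56e-09; adjusted p = 0.287 with an estimated correlation). Cyclin CCNB2 stood at 0.55 ± 0.43 with both cytokines (SD, n = 3) against 2.75 ± 0.89 with vehicle (adjusted p = 0.164). The list mean varied as widely among the vehicle arrays, from 0.62 on replicate 2 to −0.68 on replicate 3, and was −1.22 to −0.77 with both cytokines. On the 3 arrays that lay apart on the first component the structural extracellular matrix list stood lowest, at −1.04, −0.89 and −0.81 from the vehicle mean, against −0.09 to 0.75 on the other 9.

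**Figure D3:**
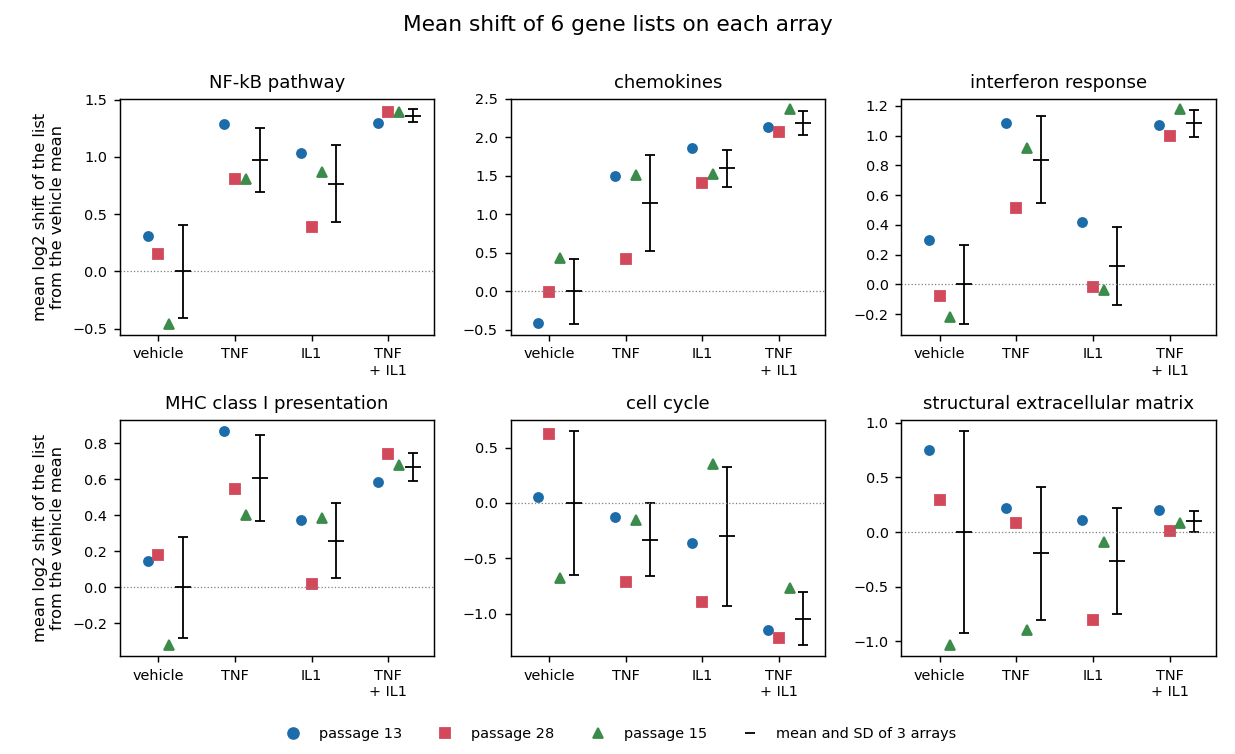
Mean log2 difference of 6 gene lists from the vehicle mean (y axis) on each array by treatment (x axis), with marker shape for the passage and black bars for the mean and SD of 3 arrays. The interferon-response mean is 0.51 to 1.09 on the TNFα arrays, −0.04 to 0.42 on the IL1β arrays and 1.00 to 1.18 on the arrays with both cytokines.

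Smaller shifts marked 5 further lists with both cytokines. Decidualization-associated genes were higher (0 of 34 past, 4 up adjusted over the list alone; median 0.43, adjusted p = 0.00143; adjusted p = 0.111 with an estimated correlation), with the decoy receptor TNFRSF11B at 2.02 ± 0.36 (adjusted p = 0.0659). In prostaglandin synthesis and reception PTGES, the inducible prostaglandin E synthase, rose by 3.01 ± 0.37 (adjusted p = 0.0114), 1 of 24 members past, with 3 up and 1 down adjusted over the list alone (median 0.21, adjusted p = 0.0205; adjusted p = 0.0863 with an estimated correlation). Matrix proteases had CTSS up of 31, by 3.45 ± 0.30, and 3 up adjusted over the list alone (median 0.23, adjusted p = 0.0199; adjusted p = 0.495 with an estimated correlation). Angiogenesis genes (0 of 25 past, 3 up adjusted over the list alone; median 0.02, adjusted p = 0.00960) included FGF2 at 1.40 ± 0.23 (adjusted p = 0.0501). Cholesterol synthesis (0 of 21 past either way; median 0.30, adjusted p = 0.0248) had INSIG1 at 0.66 ± 0.32 (adjusted p = 0.423). With an estimated correlation angiogenesis had adjusted p = 0.261 and cholesterol synthesis adjusted p = 0.495. Leaving out passage 13 ended the cholesterol call (adjusted p = 0.549), passage 28 the prostaglandin call (0.0751), and passage 15 the protease (0.505), angiogenesis (0.0873) and cholesterol (0.123) calls. Those last 3 calls also ended without the 3 arrays that lay apart (adjusted p = 0.334, 0.0747 and 0.147).

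The other 14 lists did not pass with both cytokines. In tryptophan, kynurenine and nitric oxide metabolism 2 of 12 genes rose, in both adjustments. They were kynureninase KYNU (3.23 ± 0.52, adjusted p = 0.0431) and GTP cyclohydrolase GCH1 (2.65 ± 0.42, adjusted p = 0.0399), while the list gave adjusted p = 0.107. Among 24 adhesion molecules ICAM2 (1.75 ± 0.27) and NINJ1 (1.36 ± 0.22) rose and ITGA4 fell, with 3 up and 1 down adjusted over the list alone (median −0.01, mean 0.02, adjusted p = 0.308). Oxidative stress genes had SOD2 up of 26 and 5 up adjusted over the list alone (median −0.04, mean 0.52, adjusted p = 0.0524). Steroid receptor and metabolism genes had HSD11B1 up of 31, with 1 up and 1 down adjusted over the list alone (median −0.01, mean 0.09, adjusted p = 0.856). No member passed in structural extracellular matrix (41 genes, median −0.05, mean 0.10, adjusted p = 0.376) or complement (14 genes, median −0.11, mean 0.33, adjusted p = 0.419). Nor did any pass in apoptosis (26 genes, median 0.15, adjusted p = 0.376), heat shock and unfolded protein response (25 genes, median −0.02, mean 0.00, adjusted p = 0.881) or contractile genes (22 genes, median −0.23, adjusted p = 0.640). Adjusted over the list alone, complement and apoptosis each had 2 up, heat shock 1 up and 2 down, and the others 0. Of the cell type markers, epithelial keratin KRT18 fell by 1.58 (adjusted p = 0.0447) as 1 of 12, with 1 up and 4 down adjusted over the list alone (median −0.63, adjusted p = 0.126). Stromal fibroblast (14 genes, median 0.05, adjusted p = 0.138), leukocyte (15 genes, 0.25, 0.176), endothelial (10 genes, −0.12 with a mean of 0.01, 0.606) and smooth muscle markers (9 genes, −0.18, 0.705) had no member past, and adjusted over the list alone 1 up, 1 down, 0 and 0. The epithelial list passed without passage 13 (adjusted p = 0.0291) or passage 28 (0.0327). Stromal fibroblast markers (0.0291) and structural matrix (0.0202) passed without passage 13. Oxidative stress (0.00488) and tryptophan metabolism (0.0219) passed without passage 15. Oxidative stress also passed with quantile normalization (0.0378) and with the component 1 score as a covariate (0.0288). It passed too without the 3 arrays that lay apart (0.00851), where structural matrix passed as lower (0.0125). With fry, which tests a list against no change, oxidative stress passed (adjusted p = 0.0289). Of the lists called by camera, fry did not call cell cycle (0.0809), decidualization (0.0809), angiogenesis (0.143), proteases (0.494) or cholesterol synthesis (0.548). Complement passed without dim probes (0.0126), and stromal (0.0378) and epithelial markers (0.0413) with quantile normalization.

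The responses to the single cytokines shared 3 probes in the same direction, 2 for HSD11B1 and 1 for SOD2, where independent lists of these sizes, without shared controls, would share 0.00123. Unchanged simulated groups set against the same simulated vehicle arrays shared at most 0, which follows from their having almost no calls and so tests little. Across 48012 probes the log2 changes correlated with r = 0.623 and had a covariance of 0.203. The vehicle arrays spread more widely (root mean square SD 0.786) than those with TNFα (0.608) or IL1β (0.594). Unchanged groups simulated with these spreads, a test chosen after seeing the data, gave r = 0.631 and a covariance of 0.206. With these spreads the shared vehicle arrays alone could give the whole correlation. A simulation without a separate spread per group gave r = 0.49998 and a covariance of 0.133, which left 0.0699 of the observed covariance above it. How much of the correlation the shared arrays gave therefore depended on the spread assumed and was not settled. The 3 vehicle arrays were not split to give each cytokine its own controls. Of the probes called with TNFα 22 of 25, and with IL1β 3 of 3, were also called with both cytokines, against the same vehicle arrays. The overlap was 1 probe without passage 15, and 0 without passage 13 or passage 28.

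Adding IL1β to TNFα gave 2729 probes at unadjusted p under 0.05 by limma, against 2684 by chance. It changed 1 probe past the threshold, a probe not listed with a gene that rose by 4.07 ± 0.39 (adjusted p = 0.0494). With limma it did not pass with the passage as a block (0 probes, 2582 at unadjusted p under 0.05), whichever 1 of the 6 arrays compared was left out (1891 to 2412) or in those arrays alone (5501). CXCL2 was 6.69 ± 0.20 with both cytokines (SD, n = 3) and 1.76 ± 1.58 with TNFα, a difference of 4.93 ± 0.71 (SE) with adjusted p = 0.251. As lists, chemokines were higher (0 of 21 past, 5 up adjusted over the list alone; median 0.52, adjusted p = 1.19e-07; adjusted p = 0.323 with an estimated correlation). Cell cycle was lower (0 of 45 past either way; median −0.71, adjusted p = 1.54e-06; adjusted p = 0.542 with an estimated correlation). In all, 9 lists passed, and 0 with an estimated correlation.

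Adding TNFα to IL1β changed 0 probes by limma (2347 at unadjusted p under 0.05 against 2684 by chance, lowest adjusted p = 0.188). CCL5 was 5.70 ± 0.31 with both cytokines (SD, n = 3) and 1.28 ± 0.52 with IL1β, a difference of 4.42 ± 0.60 with adjusted p = 0.206, and BST2 differed by 2.92 ± 0.39 (adjusted p = 0.188). The interferon-response list was higher, with 32 of 42 genes above every IL1β array and 1 below, where chance gives 2.1 each way. Of them 0 passed, and 19 rose adjusted over the list alone (median 0.69, adjusted p = 9.25e-31; adjusted p = 0.104 with an estimated correlation). Cholesterol synthesis was higher (0 of 21 past either way; median 0.55, adjusted p = 1.4e-06) and cell cycle lower (0 of 45 past either way; median −0.58, adjusted p = 4.62e-13). Each had adjusted p = 0.244 with an estimated correlation. In all, 10 lists passed, and 0 with an estimated correlation.

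TNFα and IL1β were also set against each other directly. limma called 0 probes (2706 at unadjusted p under 0.05 against 2684 by chance, lowest adjusted p = 0.222). CCL5 stood at 6.34 ± 1.23 with TNFα (SD, n = 3) and 1.28 ± 0.52 with IL1β (difference 5.06 ± 0.60, adjusted p = 0.222). IL32 differed by 2.39 ± 0.33 and EBI3 by 2.24 ± 0.31 (adjusted p = 0.222 for each). CXCL2 stood at 1.76 ± 1.58 and 5.55 ± 0.39 (difference −3.78 ± 0.71, adjusted p = 0.567). The interferon-response list was higher with TNFα than with IL1β (0 of 42 past, 6 up adjusted over the list alone; median 0.60, adjusted p = 6.97e-14). Also higher were MHC class I presentation (0 of 18 past either way; median 0.31, adjusted p = 0.0184) and cholesterol synthesis (0 of 21 past either way; median 0.61, adjusted p = 1.58e-05). Chemokines were lower (0 of 21 past, 1 up and 1 down adjusted over the list alone; median −0.26, adjusted p = 0.000172). Each of the 4 had adjusted p = 0.519 with an estimated correlation. Without TNFα replicate 2, 5 probes passed, among them CCL5 (5.77, adjusted p = 0.0419), the lymphocyte survival factor TNFSF13B (2.39, adjusted p = 0.0480) and CRABP2 (−1.85, adjusted p = 0.0480). Without IL1β replicate 2, 1 passed, TXNDC8 (3.96, adjusted p = 0.0366). TNFSF13B and TXNDC8 were chosen after their values were seen.

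The interaction asked whether the cytokines combined multiplicatively. limma called 0 probes (1927 at unadjusted p under 0.05 against 2684 by chance, lowest adjusted p = 0.843). HSD11B1, raised by each cytokine, had an interaction of −3.48 ± 0.67 (adjusted p = 0.843). CXCL8, at 8.50 ± 1.46 with TNFα, 9.10 ± 0.13 with IL1β and 9.39 ± 0.08 with both (SD, n = 3), had −3.70 ± 0.80 (adjusted p = 0.914). On TNFα replicate 2, the passage 28 culture, CXCL8 was 6.82 against 9.20 and 9.49 on the other TNFα arrays, and without that array its interaction passed at −4.54 (adjusted p = 0.00940), the 1 probe to do so. CXCL8 ranked 1 to 3 by signal among all probes on each array with both cytokines and equalled the highest value, 9.48, on replicate 2. For CXCL8 a signal near its upper limit would make the interaction negative. HSD11B1 was not near that limit with both cytokines, and its interaction did not pass in limma (adjusted p = 0.843). These values therefore do not show that the cytokines combined less than multiplicatively.

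Genes of the cytokine receptors and reference genes were followed in every comparison. TNF itself differed from vehicle by −0.07, −0.08 and −0.01 with TNFα, IL1β and both, its receptor TNFRSF1A by −0.19, −0.08 and 0.22, and the receptor TNFRSF1B by 0.51, 0.36 and 1.14 (SE 0.47, adjusted p = 0.348 for both). The telomerase gene TERT differed by 0.11, −0.19 and −0.12, ACTB by −0.09, −0.07 and −0.01, and GAPDH by −0.01, −0.09 and −0.29 (SE 0.15, adjusted p = 0.458 for both). None of these differences passed the test.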

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

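The tests of the cell cycle pattern were chosen only after the result was seen; the splits and regroupings of arrays were planned.

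The following lists passed the interaction test in limma camera at the preset correlation, which asks whether the effect of 1 cytokine differed with the other present. With an estimated correlation none passed. Splits or regroupings of the arrays were not run for the interaction of lists. NF-kB genes had a median interaction of −0.27 over 27 genes (adjusted p = 0.000815; adjusted p = 0.718 with an estimated correlation). Chemokines had −0.28 over 21 genes and inflammatory cytokines −0.26 over 25 (adjusted p = 0.00554 for each; adjusted p = 0.718 with an estimated correlation). Structural extracellular matrix had 0.55 over 41 genes (adjusted p = 0.00141; adjusted p = 0.776 with an estimated correlation). Cell cycle had −0.25 over 45 genes (adjusted p = 0.00554; adjusted p = 0.776 with an estimated correlation). No single member of these lists passed, and adjusted over the list alone 1 NF-kB gene, 2 chemokines and 3 cytokines were lower and 1 cytokine higher. The matrix list also stood lowest on the 3 arrays that lay apart on the first component. The chemokine list holds CXCL8, whose signal was near the highest of each array with both cytokines.

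The cell cycle list was lower with both cytokines than with vehicle. With the component 1 score as a covariate its median was −1.10, against −1.02 without it over members with a value on every array. It passed in camera with the preset correlation (adjusted p = 2.44e-07) and not with an estimated correlation (adjusted p = 0.403). Treatment groups held 3.03% of the variance of the score, so the covariate could move the median little. This argues only against a linear shift with the score as the whole cause, not against other differences between arrays. Its mean ranged over 1.30 among the 3 vehicle arrays, more than the group difference of −1.05, although 3 of 3 arrays with both cytokines lay below every vehicle array (exact permutation p = 0.1, the smallest possible). A spread between cultures that does not follow treatment cannot be told apart from a treatment effect with 3 vehicle arrays.

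Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The real split gave 25 probes for TNFα, 3 for IL1β and 133 for both cytokines against vehicle, 1 of the 10 splits each time, and the highest of the other splits gave 1. The other splits mixed treated and vehicle arrays, which widens the spread within groups wherever treatment acts. Their low probe counts therefore test little. The lists gave 8, 10 and 12, again 1 of 10 splits each, against at most 7, 7 and 9 in other splits. Both cytokines against TNFα gave 1 probe, 1 of 10 splits, and at most 0 otherwise. For both cytokines against IL1β and for TNFα against IL1β the real split gave 0 probes, so all 10 splits gave as many, and the highest other gave 1. The 3 other splits that part every passage pair gave at most 1 probe. For the interaction all 40 regroupings of the 12 arrays gave at least the 0 probes of the real grouping. Any count is at least 0, so wherever the real count was 0 the splits and regroupings could not test chance. The overlap of 3 probes between TNFα and IL1β was reached by 1 of 40 regroupings, the real one, and the highest other gave 1. This tests little, because the regroupings mixed treated and vehicle arrays and did not keep the passages together. Other splits of the compared arrays called at most 1 probe and so had almost nothing to share. The regroupings therefore do not exclude chance. The overlap was 0 without passage 13 or 28 and 0 at an adjusted p under 0.01.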

How the results depend on the processing

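Leaving out the 3 arrays that lay apart and using the component 1 score as a covariate were chosen after seeing the data; the other alternatives were planned. Over the planned and added settings 1333 of 1494 values of named genes kept their side of the threshold. Of the rest 100 lost the call, 61 gained one and 0 calls reversed. Leaving out arrays or passages, 843 of 1129 kept their side, 281 lost the call, 5 gained one and 0 calls reversed. These totals include genes not called in the main fit, which could not lose a call, so they overstate how stable the calls were. With both cytokines, calls were kept in 5 of 16 alternatives for NCF4 and in 20 of 21 for HSD11B1. For gene lists the settings left 466 of 540 in place, with 54 lost, 19 gained and 1 reversed, and leaving out passages left 203 of 234, with 15 lost, 13 gained and 3 reversed. Lists were tested again without each passage, not without each single array. The block ended 17 of 52 calls of named genes and changed no other call of a named gene or list. Over all alternatives the adjusted p for TNFα ran from 0.000201 to 0.301 for HSD11B1, 0.00236 to 0.595 for CCL5, 0.00629 to 0.583 for CCL2 and 0.00186 to 0.558 for EBI3. It ran from 0.000812 to 0.537 for SOD2 with IL1β, and with both cytokines from 2.1e-05 to 0.135 for HSD11B1 and from 0.00198 to 0.214 for CCL5.

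The probe counts were 25, 3 and 133 for TNFα, IL1β and both cytokines against vehicle and 1 for both cytokines against TNFα. They were 52, 6, 206 and 3 with the offset, where the added genes against TNFα were GNA15 and DCLK3. Without dim probes they were 50, 8 and 248, with fewer probes to adjust over, and with trend and robust settings 57, 8, 219 and 2. Array weights gave 5 for IL1β, 1200 for both cytokines (632 higher and 568 lower, all 133 included), 45 against TNFα and 41 against IL1β. The block gave 13 for TNFα, 87 for both cytokines and 0 against TNFα (limma, 2582 at unadjusted p under 0.05). Quantile normalization gave 2 against TNFα, adding DCLK3 (2.69), and 126 higher to 22 lower for both cytokines, against 101 to 32. The compared groups alone gave 0, 0, 24 and 0 (limma, 2669, 2937, 5821 and 5501 at unadjusted p under 0.05, where chance gives 2684), with fewer arrays behind the spread. Without the 3 arrays apart the counts were 0, 0 and 77 (5945, 7277 and 11686), and 1 against IL1β. Both cytokines against TNFα gave 1 probe there too, another and lower (−4.31). With the score as a covariate they were 61, 1, 785 and 0 (5034 for the last at unadjusted p under 0.05), all 25 and all 133 calls included. Quantile normalization, median centring, probes with all values and 1 probe per gene gave 23 to 37, 3 and 101 to 152 probes against vehicle. At an adjusted p under 0.01 the overlap was 0. The cause was not tested where none is given.

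Leaving out arrays or passages gave 0 to 42 probes for TNFα (without passage 13 or 28, and without TNFα replicate 2), 0 to 3 for IL1β, 4 to 137 for both cytokines (without passage 28 or 15, and without vehicle replicate 3), 0 against TNFα, 0 to 5 for TNFα against IL1β, 0 to 1 for the interaction and 0 to 1 for the overlap. Without a passage each group held 2 arrays. DCLK3, GNA15 and SP8 were chosen after their values were seen; SP8 (−3.43, adjusted p = 0.0341) passed for IL1β without IL1β replicate 1.

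With an estimated correlation 0, 0 and 4 lists passed, and with fry 4, 0 and 8, against 8, 10 and 12. The signed log10 p of structural matrix with both cytokines turned from 0.538 to −2.32 without the 3 arrays apart (adjusted p = 0.0125), where that list was also called lower for TNFα (−3.51, adjusted p = 0.00114) and IL1β (−4.09, adjusted p = 0.000529). For cell cycle it was 0.798 for TNFα and 2.82 for IL1β without passage 28 (without passage 15, −7.73 and −6.55), against −2.31 and −0.895, and for proteases with IL1β −0.177 without passage 15 and 3.48 without passage 28, against 2.15. Signal limits the dim probes: 52 of the 133 calls lay below the median signal, and the offset brought ADAMTS18 from −3.18 to −1.05.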

Other observations

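The tests of the component 1 arrays, the interferon pattern and the passages were chosen only after the result was seen, and genes named here fall outside the naming rule and were chosen after their values were seen.

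Further genes rose with both cytokines against vehicle (limma, n = 3 per group). The chemokines CCL2 and CXCL3 rose by 2.81 ± 0.38 and 2.80 ± 0.40 (adjusted p = 0.0192 and 0.0255). TNIP3, which restrains NF-kB signalling, rose by 3.16 ± 0.42 (adjusted p = 0.0181) and the ubiquitin-like protein UBD by 3.06 ± 0.45 (adjusted p = 0.0290). The transcription factor CEBPD rose by 2.47 ± 0.30 (adjusted p = 0.0102), NAMPT, an enzyme of NAD synthesis, by 2.29 ± 0.37 (adjusted p = 0.0424), and TNFAIP6, a hyaluronan-binding protein, by 1.76 ± 0.24 (adjusted p = 0.0195). The G protein subunit GNA15 rose by 3.49 ± 0.35 (adjusted p = 0.00542) and the adenosine receptor ADORA2A by 2.76 ± 0.37 (adjusted p = 0.0177). Of the 133 called probes 59 had no single gene, and among them the largest changes were 7.14 ± 0.83 and −5.49 ± 0.53 (adjusted p = 0.00944 and 0.00599).

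Between passages limma called 0 of 48012 probes, for passage 28 against passages 13 and 15 (1269 at unadjusted p under 0.05, lowest adjusted p = 0.610) and for passage 15 against 13 (2825, lowest adjusted p = 0.412). Chance gives 2401 probes at an unadjusted p under 0.05 there. At passage 28 the interferon-response list stood at −0.20 (camera adjusted p = 6e-08), chemokines at −0.31 (adjusted p = 0.000284) and cholesterol synthesis at 0.25 (adjusted p = 1.46e-06). Each had adjusted p = 0.409 with an estimated correlation. NF-kB genes (0.0404) and inflammatory cytokines (0.0164) also passed as lower. Contractile genes (0.0404), epithelial (0.0346) and smooth muscle markers (0.0351) passed as higher. None of these passed with an estimated correlation (adjusted p = 0.409 to 0.723).

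Vehicle replicate 3, TNFα replicate 3 and IL1β replicate 2 lay apart from the others at the high end of the first component. Vehicle replicate 1 lay apart at its low end (−83.7) and stayed in the fits that left out those 3 arrays. Treatment groups held 3.03% of the variance of the score (permutation p = 0.993), which argues against cytokine treatment, and passages held 31.1% (permutation p = 0.174), while replicate 3 of IL1β and of both cytokines, also passage 15, lay at −21.5 and −15.2. A candidate explanation is a signal that depends on transcript length, such as RNA quality or labelling yield would give: per 100 score units the median slope of 34 genes with very long mRNAs was −0.71 and that of 53 ribosomal protein genes 0.81, a difference of −1.51. The first lay at percentile 0.01 and the other at percentile 100 of 10000 random lists of like signal. RNA quality measures were not used here, so this stays a hypothesis.

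The interferon-response list was higher with TNFα than with IL1β. With the score on the first component as a covariate its median was 0.59, against 0.60 without. It passed in camera with the preset correlation (adjusted p = 3.73e-09) and not with an estimated correlation (adjusted p = 0.712). Treatment groups held 3.03% of the variance of the score, so the covariate could move the median little. This argues only against a linear shift with the score as the whole cause. On 3 of 3 TNFα arrays the list mean lay above every IL1β array (exact permutation p = 0.1). An interferon transcript raised by TNFα was looked for: 0 of 13 measured interferon genes passed (limma, lowest adjusted p = 0.732), and IFNB1 differed from vehicle by −0.35 ± 0.24. Their mean log2 signals with TNFα ran from −4.35 (IFNA21) to 1.71 (IFNA2), with IFNB1 at 0.44. The files carry no detection calls, so a rise in probes this dim could have been missed. Cells were sampled at 48 h only, so an earlier interferon transcript cannot be told apart from none.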
